A study of Mus musculus with 17 samples.

How the data were processed

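RNA of mouse liver was hybridised to Illumina bead arrays. Per the labels, total RNA was isolated with Trizol and turned into biotinylated cRNA with an Ambion kit. There were 17 arrays: 4 of healthy liver, 6 of liver with CCl4-induced fibrosis, 4 of CCl4-treated liver with FSP1 ablation and 3 of CCl4-treated liver with aSMA ablation. Replicate numbers were taken from the sample titles. Nothing in the labels says that the arrays are of separate animals, and each array was treated as a replicate.

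The values used are the deposited intensity values of the series matrix, 1 signal per probe and array, not in log units and with some values below 0. The authors read them with GenomeStudio, per the submitters' processing notes. The version of that program, its background correction and its normalization are not given in the sources used here. The upper quartile of the deposited intensities was 63.7 to 65.7 on the healthy arrays and 165.4 to 178.8 on the others, so that the healthy arrays lie on a scale of their own. A separate table of non-normalized values was not used, because its 34 columns have names that match no label.

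The design, chosen before the data were examined together with the groups, the gene lists, the rule for named genes and most alternatives, called for background correction with detection p or control probes. The usable table holds only signals, so the design's fallback was used: limma's normexp background correction with offset 50, quantile normalization between arrays and log2. The background of each array was taken as the mode of its deposited values, with the SD of the values below the mode. A probe was kept when it lay above the 95th percentile of that background on at least 3 arrays, which left 17141 of 25697 probes. Of all probes, 23978 have 1 gene symbol in the platform annotation, 0 have several and 1719 have none. Symbols were checked through Entrez identifiers, of which 23962 matched the RefSeq table, and 0 symbols changed. For a gene with several probes, the one with the highest mean over all arrays was used, and unnamed probes stayed separate, which gave 12663 features, called genes here, 11620 of them with a symbol and 1043 without. A gene whose probe was not above background on any array of one group has only a bound there. Its fold is written as "at least", computed against the higher of its own signal and the lowest signal above background on each array, together with the adjusted p of the fit.

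Each of 6 comparisons was a contrast of one limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) to all 17 arrays with group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 12663 genes and a threshold of 0.05. The comparisons are CCl4 against healthy, each ablation against CCl4, the ablations against each other, and each ablation against healthy. For 46 gene lists with 928 members, of which 735 were measured, limma's camera was run with its preset correlation and adjusted over the lists of a comparison, and camera with an estimated correlation and fry were run beside it. No list passed with an estimated correlation in any comparison. A count "adjusted over the list alone" adjusts the genes' p-values within the list.

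Named genes follow a rule: in each comparison the 10 genes with the largest rise and the 10 with the largest fall among those that passed, have 1 symbol and show no overlap between the groups' arrays, up to 4 members of each list with the smallest p, and S100a4, Acta2, Col1a1, Col3a1, Timp1, Cyp2e1 and Alb. Where fewer than 3 genes passed, the 5 with the smallest p were added.

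Signals of Xist and of Y-linked transcripts were read from the arrays, since the labels give no sex. The CCl4 arrays were therefore also used in parts, arrays 1 to 3 (Xist-positive) and arrays 4 to 6, with the other arrays as a group of their own in the fit. The probe for Alb parts the 17 arrays into a low and a high set that follows the same line within the CCl4 arrays. This set was read from the values after seeing them, has no source in the labels, and was used only as a check, in which Alb was not tested as a single gene. No slide or date is given. Because both ablations share the CCl4 arrays, the correlation and the overlap of their effects were set beside 100 simulations of unchanged groups and 20 splits of the CCl4 arrays.

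Alternatives were quantile normalization without background correction, the deposited values on the log2 scale without rescaling, centring of each array on its median, no or a stricter filter on dim probes (the 99th percentile), every probe on its own, trend and robust variances, array weights, replicate number as a block, Y-linked signal as a block, only the groups compared, and leaving out each array. Normexp with offset 16, the design's value for a table with detection p, was run in place of 50 as the second offset, since the fallback uses 50. The parts of the CCl4 arrays, the Alb set as a block, and the list tests with these, with the Y-linked block, with centring and without each array were added after the data were seen.

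The fit was tested on simulated log2 values, drawn independently for each gene from the mean and SD of the real gene. They hold no sex signal, no Alb set and no correlation between genes. Background correction, normalization and the probe filter were not tested in this way. Of genes changed by a log2 value of 1, the fit recovered 89.6% for CCl4 against healthy, 89.6% for FSP1 ablated against CCl4, 94% for aSMA ablated against CCl4, 89.6% for FSP1 against aSMA ablated, 91% for FSP1 ablated against healthy and 86.6% for aSMA ablated against healthy, with 6 to 12 false calls among 12463 unchanged genes. Of genes changed by a log2 value of 0.5, the fit recovered 68.7%, 55.2%, 46.3%, 38.8%, 53.7% and 47.8% in the same order. These shares hold for simulated noise of this kind only. They do not show that genes missing the threshold on the real arrays are unchanged. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.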

Results

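Gene expression was measured on 17 Illumina arrays of mouse liver RNA in 4 groups. There were 4 arrays of healthy liver and 6 of liver with fibrosis brought on by carbon tetrachloride (CCl4), a solvent that injures hepatocytes and scars the liver. Another 4 arrays came from CCl4-treated mice in which cells expressing FSP1 (the protein of S100a4, used as a fibroblast marker) were ablated, and 3 from CCl4-treated mice in which cells expressing aSMA (the protein of Acta2, used as a myofibroblast marker) were ablated. Between 13704 and 15568 of 25697 probes lay above background per array, and the number of arrays limits the precision. The upper quartile of the deposited intensities was 63.7 to 65.7 on the healthy arrays and 165.4 to 178.8 on the other arrays. Y-linked transcripts were high on the 4 healthy arrays and on CCl4 arrays 5 and 6, and Xist, the transcript of the inactive X chromosome, was high on CCl4 arrays 1 to 3 and on all arrays of both ablations. CCl4 array 4 showed neither signal. The probe for albumin (Alb) read 6.28 to 6.73 on the healthy arrays, the FSP1 ablated arrays and CCl4 arrays 1 to 3, and 8.60 to 9.26 on the other arrays. In healthy liver Apoa2, Serpina1a, Apoh and Fetub, also genes of proteins secreted by hepatocytes, averaged 14.63, 13.30, 12.74 and 11.80. Fgb, of the same list, was low too, at 6.56 in CCl4 liver. The Alb signal is used here to part the arrays and not read as a measure of albumin expression, and its cause was not tested. Alb stayed in the list of hepatocyte secreted proteins. Values below are normalized log2 intensities as mean ± SD, and differences are log2 fold changes with their standard errors (SE).

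Acta2, which encodes smooth muscle actin, averaged 7.71 ± 0.68 in healthy liver (n = 4), 10.35 ± 0.83 in CCl4 liver (n = 6), 7.49 ± 0.34 after FSP1 ablation (n = 4) and 8.13 after aSMA ablation (n = 3). The 3 aSMA ablated arrays read 7.69, 9.27 and 7.43, so that array 2 lay above the lowest CCl4 array at 9.11, and the 6 CCl4 arrays reached up to 11.29. The Acta2 difference between aSMA ablated and CCl4 liver was -2.22 (SE 0.48) and missed the threshold against all 6 CCl4 arrays, with adjusted p = 0.101. It was -2.83 (adjusted p = 0.00222) against CCl4 arrays 1 to 3 and -1.61 (adjusted p = 0.303) against CCl4 arrays 4 to 6, and it was -2.46 (adjusted p = 0.0143) without CCl4 array 4. With Y-linked signal as a block it was -2.37 (adjusted p = 0.0413), and with array weights -2.78 (adjusted p = 0.00157). Here and below, that block sets an ablation against CCl4 arrays 1 to 4 only, so it overlaps with the result for arrays 1 to 3. The probe for S100a4 read 6.09 to 6.39 on all 17 arrays, near background, so it checks nothing about the FSP1 ablated group.

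**Figure D1:**
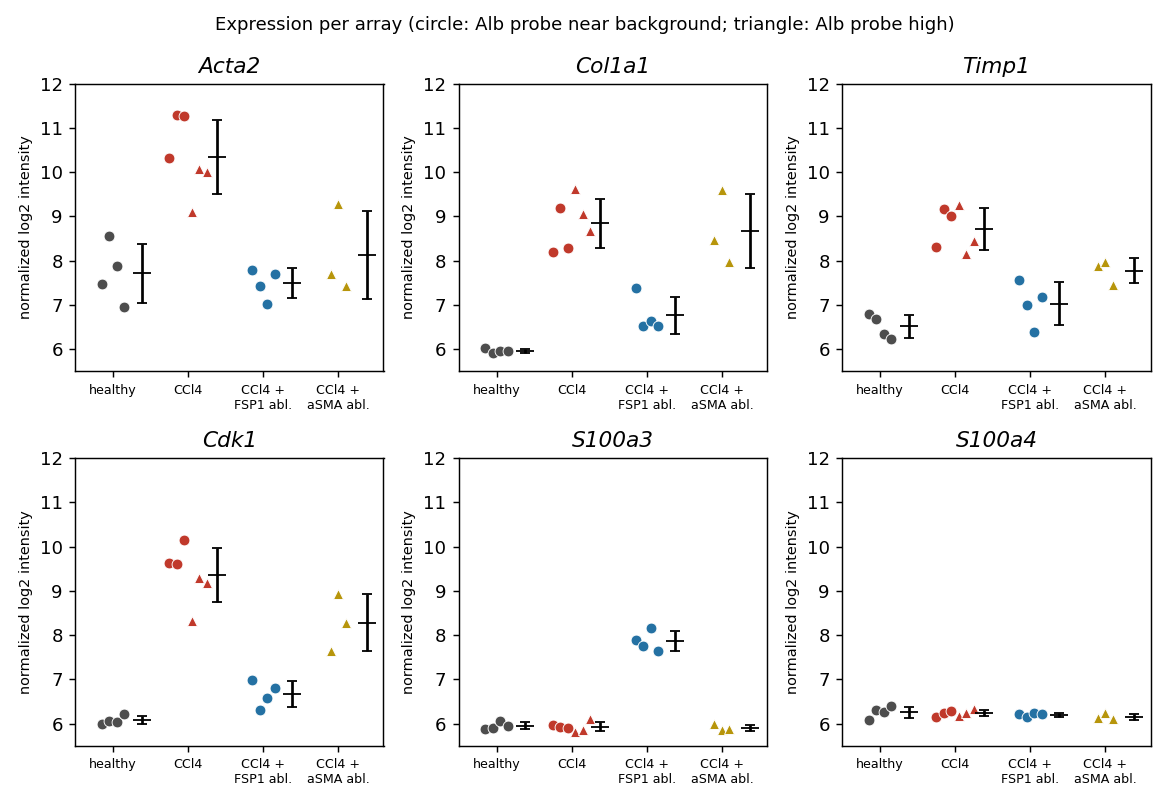
Normalized log2 intensity (vertical axes) of Acta2, Col1a1, Timp1, Cdk1, S100a3 and S100a4 in the 4 groups (horizontal axes); points are arrays, triangles mark arrays with a high Alb probe signal, and black dashes with bars are mean ± SD. S100a3 is high on the 4 FSP1 ablated arrays, at 7.63 to 8.15, and S100a4 stays between 6.09 and 6.39 on every array.

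CCl4 liver was compared with healthy liver to describe the fibrotic injury. Most measured matrix genes, genes of dividing cells and macrophage genes rose, and the genes that fell included pericentral hepatocyte markers and male-biased liver genes, though no list passed with an estimated correlation. Col1a1, the main fibrillar collagen of scar tissue, averaged 8.84 ± 0.55 (n = 6) and was at least 6.61-fold higher than in healthy liver, where it was not well above background (5.96 ± 0.04, n = 4; adjusted p = 6.27e-06). Col3a1 rose by 1.84 (SE 0.24; adjusted p = 3.86e-05) and Timp1, an inhibitor of matrix proteases, by 2.21 (SE 0.25; adjusted p = 9.94e-06). Acta2 rose by 2.63 (SE 0.44; adjusted p = 0.000326).

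Of 26 measured extracellular matrix genes, 23 rose and none fell, with 24 rising when adjusted over the list alone. Examples are Nid1 (2.77, SE 0.27) and Col4a1 (2.42, SE 0.22), parts of basement membranes, and Col5a1 at 1.81. The list passed limma's camera test (adjusted p = 3.44e-15), with adjusted p = 0.194 with an estimated correlation. Genes that process and crosslink collagen rose in 10 of 17 cases, 10 also when adjusted over the list alone, among them Lox, whose product links collagen fibres and which was at least 2.3-fold higher (adjusted p = 4.93e-05) than in healthy liver, where it was not well above background. That list had adjusted p = 7.34e-05, and adjusted p = 0.194 with an estimated correlation.

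Of 34 cell cycle genes, 32 rose and none fell, with 33 rising when adjusted over the list alone (adjusted p = 1.51e-21, and adjusted p = 0.194 with an estimated correlation). Prc1, a protein of the dividing spindle, rose by 4.52 (SE 0.42; adjusted p = 1.81e-06), Cdc20, an activator of mitotic exit, by 3.89 (SE 0.40), and Birc5, an inhibitor of apoptosis made in mitosis, by 3.37 (SE 0.30). The mitotic kinase gene Cdk1 went from 6.08 ± 0.10 (n = 4) to 9.35 ± 0.61 (n = 6). Cdkn1a and Phlda3, targets of p53, rose by 2.94 (SE 0.44; adjusted p = 0.000136) and 1.91 (SE 0.13; adjusted p = 1.71e-07).

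Monocyte and macrophage markers rose in 20 of 23 cases and none fell, with 21 rising when adjusted over the list alone (adjusted p = 1.58e-11, and adjusted p = 0.113 with an estimated correlation). They included Cd63 at 3.87 (SE 0.37), Lgals3 at 3.20 (SE 0.43), Lyz1, a lysozyme, at 1.98 and Ms4a7 at 1.20. Ly6d, the gene with the largest rise among those whose arrays did not overlap between the groups, went from 6.07 ± 0.10 (n = 4) to 11.86 ± 0.58 (n = 6), a difference of 5.79 (SE 0.39; adjusted p = 1.47e-07). Golm1, a Golgi protein, rose by 3.95 (SE 0.23; adjusted p = 3.8e-08), the calcium-binding S100a11 by 3.97 (SE 0.31) and the iron-sequestering acute phase gene Lcn2 by 4.05 (SE 0.76; adjusted p = 0.000845), and by 5.28 (adjusted p = 2.5e-07) without healthy array 1. Ribosomal protein genes rose in 8 of 12 cases, 11 when adjusted over the list alone (adjusted p = 0.000153, and adjusted p = 0.284 with an estimated correlation). This list does not measure RNA quality, for which no measure was used here.

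Of 15 pericentral hepatocyte markers, 8 fell and 1 rose, with 10 falling when adjusted over the list alone (adjusted p = 0.00181, and adjusted p = 0.284 with an estimated correlation). The glutamate transporter gene Slc1a2 fell by 4.54 (SE 0.27; adjusted p = 5.05e-08), Oat, which degrades ornithine, fell by 2.87 (SE 0.41; adjusted p = 8.92e-05), and glutamine synthetase, Glul, fell by 0.98. Cyp2e1, which turns CCl4 into its toxic radical, went from 14.58 ± 0.05 (n = 4) to 13.06 ± 0.96 (n = 6), a change of -1.52 (SE 0.38; adjusted p = 0.00633) that was -0.96 (adjusted p = 0.0591) on the deposited scale. For CCl4 arrays 5 and 6 alone, which share the Y-linked signal of the healthy arrays, it was -0.79 (adjusted p = 0.113). With that signal as a block the change rests on the same CCl4 arrays, so it is the same -0.79 by construction (adjusted p = 0.232). The change was -0.78 (adjusted p = 0.06) for CCl4 arrays 4 to 6 and -2.27 (adjusted p = 4.23e-05) for CCl4 arrays 1 to 3. All 12 male-biased liver genes fell, 12 also when adjusted over the list alone, with a median of -2.66 (adjusted p = 3.19e-08, and adjusted p = 0.251 with an estimated correlation). The steroid dehydrogenase gene Hsd3b5 went from 12.66 ± 0.56 (n = 4) to 7.41 ± 1.88 (n = 6) and Susd4 fell by 2.63 (SE 0.12; adjusted p = 1.95e-09). The healthy arrays are all Y-positive and 2 of 6 CCl4 arrays are, and against those 2 arrays Hsd3b5 differed by -2.82 (adjusted p = 7.64e-06) and Susd4 by -2.41 (adjusted p = 4.55e-07).

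In all, 4387 of 12663 genes (34.6%) passed between CCl4 and healthy liver, 2165 higher and 2222 lower, and 472 of the former and 193 of the latter changed at least 2-fold. On the deposited scale, where the median of all genes was 1.03 higher in CCl4 liver, 8583 genes passed, 8515 higher and 68 lower, and with each array centred on its median, where it was 0.32 higher, 7123 passed, 6367 higher and 756 lower. With Y-linked signal as a block 2479 genes passed, and within the CCl4 arrays 4553 passed for arrays 1 to 3 and 3502 for arrays 4 to 6, of which 2409 were shared with the same sign.

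**Figure D2:**
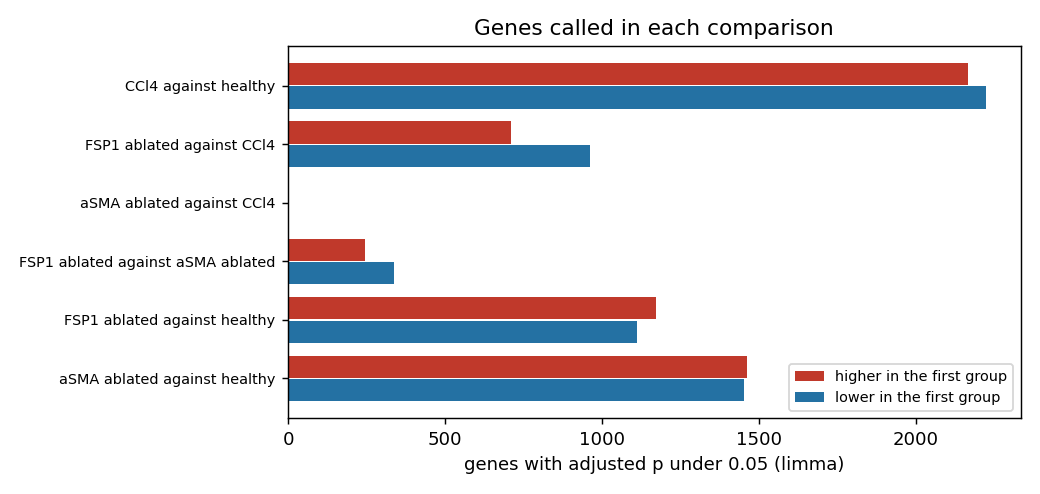
Genes with adjusted p under 0.05 in each of the 6 comparisons (bars; counts of genes, higher and lower in the group named first). The counts run from 1 for aSMA ablated against CCl4 liver to 4387 for CCl4 against healthy liver.

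FSP1 ablated livers were compared with CCl4 livers to describe what the loss of FSP1-expressing cells changed in the injured liver. The genes that fell included most matrix and cell cycle genes and some contractile and interferon genes, and those that rose some genes of glucose metabolism, though no list passed with an estimated correlation. Acta2 fell by 2.86 (SE 0.44; adjusted p = 0.000444), from 10.35 ± 0.83 (n = 6) to 7.49 ± 0.34 (n = 4), Col1a1 fell by 2.07 (SE 0.30; adjusted p = 0.000311), Col3a1 fell by 1.77 (SE 0.24; adjusted p = 0.000158) and Timp1 fell by 1.70 (SE 0.25; adjusted p = 0.000272). S100a4 differed by -0.02 (adjusted p = 0.848).

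Extracellular matrix genes fell in 17 of 26 cases and none rose, with 18 falling when adjusted over the list alone (adjusted p = 2.13e-10, and adjusted p = 0.28 with an estimated correlation). Sparc, which binds collagen, fell by 1.92 (SE 0.26; adjusted p = 0.000185), Col5a1 fell by 1.41 and the matrix glycoprotein gene Tnc fell by 0.84. Of 17 genes that process collagen 9 fell, 9 also when adjusted over the list alone, with Pcolce at -1.15 and the collagen chaperone Serpinh1 at -1.14 (adjusted p = 2.4e-05, and adjusted p = 0.28 with an estimated correlation). Of 13 contractile genes 7 fell, 8 when adjusted over the list alone, with Vim, an intermediate filament of mesenchymal cells, at -1.18 (adjusted p = 3.29e-05, and adjusted p = 0.28 with an estimated correlation). The 15 stellate cell markers had a median of 0.00 and did not pass as a list (adjusted p = 0.554).

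Of 34 cell cycle genes 31 fell and none rose, with 32 falling when adjusted over the list alone, at a median of -1.46 (adjusted p = 1.53e-34, and adjusted p = 0.204 with an estimated correlation). Prc1 fell by 3.44 (SE 0.42; adjusted p = 7e-05), Birc5 fell by 3.02 (SE 0.30; adjusted p = 1.45e-05), Mcm5, part of the helicase that opens DNA for replication, fell by 2.92 (SE 0.28; adjusted p = 9.3e-06), and the transcription factor gene E2f1 fell by 1.41 (SE 0.09; adjusted p = 1.46e-07). Of 26 interferon response genes 7 fell, 11 when adjusted over the list alone, with Dhx58, a sensor of viral RNA, at -0.91 (SE 0.18; adjusted p = 0.00274). That list had adjusted p = 1.37e-05, and adjusted p = 0.412 with an estimated correlation.

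Of 13 genes of glucose metabolism 5 rose and none fell, with 7 rising when adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.28 with an estimated correlation). Pklr, the pyruvate kinase of liver, rose by 2.28 (SE 0.40; adjusted p = 0.00132) and Khk, which phosphorylates fructose, by 1.27 (SE 0.23; adjusted p = 0.0019). Acaca, which makes malonyl-CoA for fatty acid synthesis, went from 10.50 ± 0.40 (n = 6) to 12.49 ± 0.71 (n = 4) and rose by 1.99 (SE 0.29; adjusted p = 0.000266), and Fasn, the fatty acid synthase, rose by 1.09 (SE 0.20; adjusted p = 0.00164). The steroid hydroxylase gene Cyp17a1 rose by 3.63 (SE 0.53; adjusted p = 0.000277) and Cux2, a transcription factor of female liver, by 2.25 (SE 0.13; adjusted p = 7e-08). S100a3, a gene close to S100a4 in the S100 cluster, was at least 3.47-fold higher than in CCl4 liver, where it was not well above background (adjusted p = 4.17e-09), and reached 7.63 to 8.15 on the 4 FSP1 ablated arrays against 5.81 to 6.10 on the other 13. The glutathione transferase genes Gsta1 and Gsta2 fell by 3.05 (SE 0.31; adjusted p = 1.45e-05) and fell by 1.97.

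In all, 1673 genes (13.2%) passed between FSP1 ablated and CCl4 liver, 711 higher and 962 lower, of which 72 and 221 changed at least 2-fold. Without FSP1 ablated array 2 the count was 1111. Against CCl4 arrays 1 to 3, which share the Xist signal and the low Alb signal of the FSP1 ablated arrays, 1691 genes passed, against arrays 4 to 6 2172, and 815 passed in both with the same sign, 287 higher and 528 lower. Acta2 differed by -3.47 and -2.25 in these comparisons, Col1a1 by -1.79 and -2.35, and Acaca by 1.96 and 2.02.

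aSMA ablated livers were compared with CCl4 livers to describe what the loss of aSMA-expressing cells changed. By limma 1 gene passed, Bex3, a small neuronal and stress-related adaptor gene, which went from 8.71 ± 0.14 (n = 6) to 8.01 ± 0.08 (n = 3) and fell by 0.70 (SE 0.10; adjusted p = 0.0265), and fell by 0.80 (adjusted p = 0.261) on the deposited scale. Against CCl4 arrays 1 to 3 it differed by -0.71 (adjusted p = 0.00181) and against arrays 4 to 6 by -0.69 (adjusted p = 0.0565). Bex3 no longer passed when any aSMA ablated array, or CCl4 array 1, 2, 3 or 6, was left out, with an adjusted p of up to 0.411. Without the adjustment 1434 genes had p under 0.05. Col1a1 averaged 8.68 ± 0.83 (n = 3) and differed by -0.16 (SE 0.33; adjusted p = 0.916), Col3a1 by -0.46 (SE 0.26; adjusted p = 0.551) and Timp1 by -0.96 (SE 0.27; adjusted p = 0.185). Against CCl4 arrays 1 to 3 Timp1 differed by -1.06 (adjusted p = 0.046) and Col1a1 by 0.12 (adjusted p = 0.908). Against arrays 4 to 6 they differed by -0.85 (adjusted p = 0.457) and -0.44 (adjusted p = 0.839). Timp1 differed by -1.17 (adjusted p = 0.042) with Y-linked signal as a block and by -1.13 (adjusted p = 0.00695) with array weights.

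As a list, cell cycle genes fell, with a median of -0.76 and adjusted p = 4.63e-24, and adjusted p = 0.204 with an estimated correlation. None of its 34 members passed over all genes, and 26 fell when adjusted over the list alone. Among them the replication helicase genes Mcm2 and Mcm5 differed by -1.08 (SE 0.20; adjusted p = 0.0695) and -1.55 (SE 0.30; adjusted p = 0.0797), and E2f1 by -0.51 (adjusted p = 0.0794). Without CCl4 array 4 they differed by -1.21 (adjusted p = 0.003), -1.77 (adjusted p = 0.003) and -0.53 (adjusted p = 0.0212). Against CCl4 arrays 1 to 3 they differed by -1.39 (adjusted p = 0.000576), -1.94 (adjusted p = 0.00143) and -0.60 (adjusted p = 0.00334). Against CCl4 arrays 4 to 6 they differed by -0.77 (adjusted p = 0.15), -1.15 (adjusted p = 0.214) and -0.42 (adjusted p = 0.213). With Y-linked signal as a block, and so against CCl4 arrays 1 to 4, they passed (adjusted p = 0.0285, 0.0401 and 0.0301). They also passed with array weights (adjusted p = 0.000836, 0.0015 and 0.00157).

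Under aSMA ablation against CCl4 liver cytochrome P450 and xenobiotic genes rose as a list, with a median of 0.61 and adjusted p = 2.24e-07, and adjusted p = 0.204 with an estimated correlation. None of these 28 passed over all genes and 3 rose when adjusted over the list alone, and the nuclear receptor genes Nr1i3 and Nr1i2, which switch on drug metabolism, differed by 0.94 (adjusted p = 0.173) and 0.69 (adjusted p = 0.175). They differed by 1.03 (adjusted p = 0.0433) and 0.96 (adjusted p = 0.00372) against CCl4 arrays 1 to 3, and by 0.85 (adjusted p = 0.419) and 0.42 (adjusted p = 0.555) against arrays 4 to 6. With array weights both passed (adjusted p = 0.00447 and 0.00301), and with Y-linked signal as a block Nr1i2 did, at 0.90 (adjusted p = 0.021), and Nr1i3 did not (adjusted p = 0.071).

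In the same comparison the lists of ribosomal protein and circadian clock genes moved. Ribosomal protein genes had a median of -0.27, with 1 lower when adjusted over the list alone (adjusted p = 8.64e-06, and adjusted p = 0.296 with an estimated correlation). Circadian clock genes, a check on the time of sampling, had a median of 0.52, with 1 higher when adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.296 with an estimated correlation). Against CCl4 arrays 4 to 6 these lists had adjusted p = 0.085 and 0.327, and the clock list had adjusted p = 0.0898 without aSMA ablated array 3.

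Periportal hepatocyte markers rose as a list of 11, with a median of 0.49 and none passing singly over all genes or when adjusted over the list alone (adjusted p = 0.000185, and adjusted p = 0.296 with an estimated correlation). Pck1, which starts the making of glucose, differed by 1.03 (adjusted p = 0.26), by 1.55 (adjusted p = 0.00643) against CCl4 arrays 1 to 3 and by 0.51 (adjusted p = 0.753) against arrays 4 to 6. With Y-linked signal as a block it differed by 1.34 (adjusted p = 0.0487), and with array weights it passed too (adjusted p = 0.00759). The 13 contractile genes fell as a list, with a median of -0.18, none passing over all genes and 3 falling when adjusted over the list alone (adjusted p = 0.00118, and adjusted p = 0.33 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, differed by -0.40 (adjusted p = 0.216), by -0.51 (adjusted p = 0.0213) against CCl4 arrays 1 to 3 and by -0.29 (adjusted p = 0.6) against arrays 4 to 6. It passed with array weights (adjusted p = 0.0119) and not with Y-linked signal as a block (adjusted p = 0.0751). Against CCl4 arrays 4 to 6 the contractile list had adjusted p = 0.0546. The 26 matrix genes had a median of -0.17 and adjusted p = 0.0119, with none passing over all genes or when adjusted over the list alone, and adjusted p = 0.7 with an estimated correlation. Against CCl4 arrays 1 to 3 the matrix list had a median of -0.09 and adjusted p = 0.398, and without aSMA ablated array 3 adjusted p = 0.813.

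The number of genes passing depended on which CCl4 arrays were used, with 1236 against arrays 1 to 3, 4 against arrays 4 to 6, which share the high Alb signal of the aSMA ablated arrays, and 2 in both with the same sign. Leaving out CCl4 array 4 gave 189 genes.

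**Figure D3:**
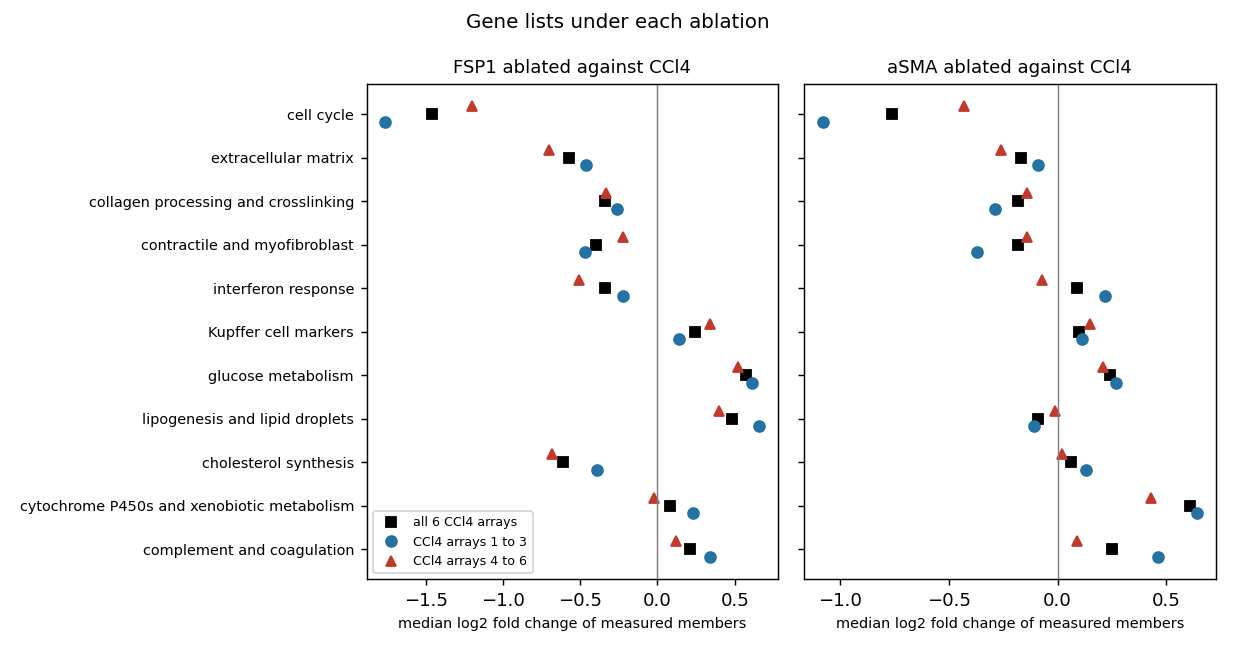
Median log2 fold change (one axis) of 11 gene lists (other axis) under FSP1 and aSMA ablation against CCl4 liver; squares use all 6 CCl4 arrays, circles arrays 1 to 3 and triangles arrays 4 to 6. The cell cycle list lies at -1.46 under FSP1 ablation and at -0.76 under aSMA ablation against all 6 arrays.

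FSP1 and aSMA ablated livers were compared directly, which tests whether the ablations differed. The genes lower after FSP1 ablation than after aSMA ablation included some matrix, cell cycle, interferon and cholesterol synthesis genes, though no list passed with an estimated correlation. E2f1 differed by -0.91 (SE 0.11; adjusted p = 0.000535), Tk1, a thymidine kinase of dividing cells, by -1.86 (SE 0.25; adjusted p = 0.0016), Lgals1, a galectin of mesenchymal cells, by -2.14 (SE 0.25; adjusted p = 0.000455), Cyp2c55 by -2.61 (SE 0.26; adjusted p = 0.000119) and Gsta1 by -2.37 (SE 0.36; adjusted p = 0.00365). Cux2 was higher by 1.73 (SE 0.16; adjusted p = 3.99e-05), Ank, a transporter of pyrophosphate, by 1.85 (SE 0.13; adjusted p = 2.47e-06), and S100a3 was at least 3.49-fold higher than after aSMA ablation, where it was not well above background (adjusted p = 4.46e-08). Acta2 differed by -0.64 (adjusted p = 0.532), Timp1 by -0.74 (adjusted p = 0.155) and S100a4 by 0.05 (adjusted p = 0.746).

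Of 34 cell cycle genes 16 were lower and none higher, 23 when adjusted over the list alone (adjusted p = 4.59e-16, and adjusted p = 0.497 with an estimated correlation). Of 26 matrix genes 6 were lower, 13 when adjusted over the list alone (adjusted p = 5.66e-07, and adjusted p = 0.497 with an estimated correlation). Col1a1 differed by -1.91 (SE 0.36; adjusted p = 0.00886), and by -1.45 (adjusted p = 0.0615) without aSMA ablated array 2. Col3a1 differed by -1.30 (SE 0.28; adjusted p = 0.0181), and by -1.14 (adjusted p = 0.11) without that array, -1.25 (adjusted p = 0.059) without aSMA ablated array 1 and -1.17 (adjusted p = 0.058) without FSP1 ablated array 2. With the Alb signal sets as a block Col1a1 differed by -1.35 (adjusted p = 0.206) and Col3a1 by -0.64 (adjusted p = 0.437). Of 26 interferon response genes 6 were lower, 8 when adjusted over the list alone (adjusted p = 3.34e-07, and adjusted p = 0.497 with an estimated correlation). Of 18 cholesterol synthesis genes 4 were lower, and 9 were lower and 1 higher when adjusted over the list alone (adjusted p = 0.000538, and adjusted p = 0.497 with an estimated correlation). The interferon gene Gbp2 differed by -0.59 (SE 0.12; adjusted p = 0.0149). The cholesterol gene Dhcr7 differed by -1.54 (SE 0.30; adjusted p = 0.0117). With the Alb signal sets as a block these 2 genes no longer passed, at -0.66 (adjusted p = 0.0718) and -0.70 (adjusted p = 0.373). Without aSMA ablated array 2 they had adjusted p = 0.0972 and 0.0841.

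Ribosomal protein genes were higher after FSP1 ablation at a median of 0.25, with 2 higher when adjusted over the list alone (adjusted p = 0.00192, and adjusted p = 0.589 with an estimated correlation). Of 6 erythroid genes 2 were lower, 3 when adjusted over the list alone, at a median of -1.13 (adjusted p = 0.00641, and adjusted p = 0.497 with an estimated correlation).

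In all, 585 genes (4.62%) passed between the ablations, 246 higher and 339 lower after FSP1 ablation, of which 33 and 122 differed at least 2-fold. The count was 97 without aSMA ablated array 2, 232 without aSMA ablated array 3, 322 without aSMA ablated array 1, 215 without FSP1 ablated array 2 and 363 without FSP1 ablated array 1. All FSP1 ablated arrays have a low and all aSMA ablated arrays a high Alb signal, and with these sets as a block, which rests on the CCl4 arrays, 302 genes passed. With each array centred on its median 836 passed, 197 higher and 639 lower, and on the deposited scale 333, 104 higher and 229 lower.

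Across the 12663 genes, which are not independent replicates, the fold changes of both ablations against CCl4 correlated with r = 0.452 and a covariance of 0.0415. In 100 simulations all arrays, the shared CCl4 arrays included, were drawn as unchanged, with each gene drawn independently. They gave a median r of 0.367, at most 0.404, and a covariance of 0.00934, at most 0.0105. Genes on real arrays vary together, so chance there can range more widely than these simulations and the simulated overlaps below. With the CCl4 arrays split so that the ablations shared none, the median r over 20 splits was 0.315, from -0.0771 to 0.456, and the median covariance 0.0315. The lowest r, with a covariance of -0.0117, set FSP1 ablation against CCl4 arrays 4 to 6 and aSMA ablation against arrays 1 to 3. In that split each ablation met the other Alb set. The reverse split, within the Alb sets, gave r = 0.329. At unadjusted p under 0.05, 477 genes were lower under both ablations, out of 1687 for FSP1 and 809 for aSMA, where independent lists give 108 and the simulations 48, at most 64. Higher under both were 210 genes, out of 1629 and 625, where independent lists give 80.4 and the simulations 47, at most 66.

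Of the 4387 genes that passed between CCl4 and healthy liver, 82.3% had a fold change of the opposite sign under FSP1 ablation, where simulated unchanged groups gave 56.9%, at most 58.3%. With CCl4 arrays split so that none was shared, the median was 79.6%, from 59.5% to 85.7%. The lowest share had genes called on CCl4 arrays 1 to 3 and the effect taken against arrays 4 to 6, and the reverse gave 79%. Under aSMA ablation 66% had the opposite sign, where simulated groups gave 56.3%, at most 57.5%, and the split median was 59.1%, from 49.5% to 67.4%. Here the lowest share had genes called on arrays 4 to 6 and the effect taken against arrays 1 to 3, and the reverse gave 54.2%. On the deposited scale, where nearly all genes that pass are higher in CCl4 than in healthy liver, the shares were 48.7% and 49.5%.

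FSP1 ablated livers were compared with healthy livers to describe how far they stood from the uninjured state. Col3a1 differed by 0.07 (adjusted p = 0.88), and by 1.32 (adjusted p = 0.0125) on the deposited scale. Timp1 differed by 0.51 (adjusted p = 0.206), by 2.26 (adjusted p = 0.000144) on the deposited scale and by 0.76 (adjusted p = 0.0309) with each array centred on its median. With array weights Timp1 passed too (adjusted p = 0.0314), and with Y-linked signal as a block it differed by -0.13 (adjusted p = 0.9). Acta2 differed by -0.22 (adjusted p = 0.788), by 0.40 (adjusted p = 0.495) with centring and by 1.07 (adjusted p = 0.109) on the deposited scale. Col1a1 was not well above background in healthy liver, and its difference did not pass (adjusted p = 0.106), while it passed on the deposited scale (adjusted p = 8.52e-06). It also passed with a smaller offset in the background correction (adjusted p = 0.0158), with no correction (adjusted p = 0.00642), with array weights (adjusted p = 0.0384) and with only the 2 groups compared (adjusted p = 0.0225).

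After FSP1 ablation Ly6d was higher than in healthy liver by 5.58 (SE 0.43; adjusted p = 1.7e-06) and Cd63 by 3.33 (SE 0.41; adjusted p = 0.00018). Monocyte and macrophage markers were higher in 19 of 23 cases and lower in none, 21 when adjusted over the list alone (adjusted p = 6.35e-13, and adjusted p = 0.133 with an estimated correlation), among them Ms4a7 at 1.03 (SE 0.15; adjusted p = 0.000489). Of 26 matrix genes 12 were higher, 12 also when adjusted over the list alone (adjusted p = 1.59e-06, and adjusted p = 0.295 with an estimated correlation), and of 34 cell cycle genes 1 was higher and 2 were lower (adjusted p = 0.395). All 12 male-biased genes were lower, 12 also when adjusted over the list alone, with Hsd3b5 at -6.43 (SE 0.78; adjusted p = 0.000169). That list had adjusted p = 6.54e-15, and adjusted p = 0.133 with an estimated correlation. Of 18 cholesterol synthesis genes 10 were lower, 14 when adjusted over the list alone, at a median of -0.91 that was 0.09 on the deposited scale (adjusted p = 3.7e-07, and adjusted p = 0.188 with an estimated correlation). Ribosomal protein genes were higher in 8 of 12 cases, 10 when adjusted over the list alone (adjusted p = 1.03e-05, and adjusted p = 0.264 with an estimated correlation). In all 2285 genes passed, 1172 higher and 1113 lower. On the deposited scale, where the median of all genes was 1.17, 9178 were higher and 60 lower, and 6110 higher and 350 lower with each array centred on its median, where it was 0.33. Each array of one group differs from each of the other in its sex signals, and with Y-linked signal as a block, which rests on the CCl4 arrays, 165 genes passed. The count was 1359 without healthy array 4, 1374 without healthy array 3, 1456 without FSP1 ablated array 2 and 1477 without FSP1 ablated array 1.

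aSMA ablated livers were compared with healthy livers for the same purpose. Col1a1 was at least 5.91-fold higher than in healthy liver, where it was not well above background (adjusted p = 0.000127), the basement membrane gene Nid1 was higher by 2.51 (SE 0.32; adjusted p = 8.45e-05) and Col6a1 by 2.35 (SE 0.27; adjusted p = 3.62e-05). Acta2 differed by 0.42 (adjusted p = 0.601), and by 1.94 (adjusted p = 0.0124) on the deposited scale. Of 26 matrix genes 22 were higher, 22 also when adjusted over the list alone (adjusted p = 4.36e-13, and adjusted p = 0.248 with an estimated correlation). Of 34 cell cycle genes 21 were higher, 23 when adjusted over the list alone, with Prc1 at 3.35 (SE 0.50; adjusted p = 0.000291) and Cdk1 at 2.20 (SE 0.34; adjusted p = 0.000396). That list had adjusted p = 4.3e-11, and adjusted p = 0.404 with an estimated correlation. Of 23 monocyte and macrophage markers 18 were higher, 19 when adjusted over the list alone, among them Fcgr1, an antibody receptor that was at least 1.62-fold higher (adjusted p = 4.39e-05) than in healthy liver, where it was not well above background. The list had adjusted p = 4.36e-13, and adjusted p = 0.0695 with an estimated correlation. Of 12 male-biased genes 11 were lower, 12 when adjusted over the list alone (adjusted p = 8.97e-11, and adjusted p = 0.248 with an estimated correlation), and Cyp4a12a differed by -6.77. Each aSMA ablated array differs from each healthy array in its sex signals, so sex cannot be told apart from the group here. Cyp4a12a read 6.04 to 6.26 on the aSMA ablated arrays and 6.59 to 6.78 on the Xist-positive CCl4 arrays 1 to 3. On the Y-positive CCl4 arrays 5 and 6 it read 12.14 and 11.63. In all 2912 genes passed, 1461 higher and 1451 lower. On the deposited scale, where the median of all genes was 1.10, 8306 were higher and 61 lower, and 6333 higher and 478 lower with each array centred on its median, where it was 0.38. With Y-linked signal as a block, which rests on the CCl4 arrays, 1358 genes passed, and without aSMA ablated array 2 1601.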

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

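The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts over other splits of the arrays were planned.

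FSP1 ablation gave 1673 genes against CCl4 liver (1111 without FSP1 ablated array 2) and aSMA ablation gave 1, a contrast that depends on the settings, since aSMA ablation gave 1688 with array weights, where FSP1 ablation gave 2301, 1405 with same-sex arrays, 220 with the sex block and 189 without CCl4 array 4. The same-sex arrays are CCl4 arrays 1 to 3, of the other Alb set than the aSMA ablated arrays. The sex block uses CCl4 arrays 1 to 4, so these counts are not separate checks. Tested directly, 585 genes changed differently under the ablations, and 302 with the Alb set block, 97, 232 and 322 without aSMA ablated array 2, 3 or 1, and 215 and 363 without FSP1 ablated array 2 or 1. Mixed sex signals and Alb sets among the CCl4 arrays as the source of all calls under FSP1 ablation are argued against, since 1691 genes passed against CCl4 arrays 1 to 3, which share both with the FSP1 ablated arrays, 1139 of them among the 1673. Arrays 1 to 3 may differ from the others in further ways, which the 1691 cannot exclude. Against both parts 815 genes passed with the same sign, in comparisons that share the FSP1 ablated arrays. Whether the mixture of CCl4 arrays hides changes under aSMA ablation cannot be told from the calls, since 2 genes passed against both kinds of array while 374 had the same sign and unadjusted p under 0.05 against both, and these comparisons share the aSMA ablated arrays. Whether the Alb set gives the 1236 genes that passed against CCl4 arrays 1 to 3 stays open too, since their folds against arrays 4 to 6 had a median of 0.14 in place of 0.64 (median ratio 0.222) at the same SE of 0.14, 959 with the same sign, and a biological difference between the ablations, which differ in Alb set, stays open. Genes chosen for passing against arrays 1 to 3 can show smaller folds against other arrays through that choice alone. For the 1691 genes chosen in this way under FSP1 ablation the medians were 0.63 and 0.39 (median ratio 0.613).

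All 12 male-biased liver genes were lower in CCl4 than in healthy liver, while the healthy arrays are all Y-positive and 2 of the 6 CCl4 arrays are. Sex alone is argued against, since the list's median was -1.40 (upper quartile -0.52) between the Y-positive CCl4 arrays and the healthy arrays. The separate scale of the healthy arrays is argued against too, since on the deposited scale the list's median lay at -4.57 (upper quartile -2.46) relative to the median of all genes. Sex may add to the size of the change, since the per-array median of the list was 10.56 and 10.41 on CCl4 arrays 5 and 6, 6.73 to 7.34 on CCl4 arrays 1 to 4 and up to 12.52 on the healthy arrays. An effect of CCl4 on these genes remains a hypothesis.

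S100a3 was high on all 4 FSP1 ablated arrays and near background on the other 13. The sex or Alb set of the arrays compared is argued against, since on the lowest FSP1 ablated array S100a3 was at least 2.98-fold above the background limit of CCl4 arrays 1 to 3, which share both and where it was above background on 0 of 3 arrays. A transgene that carries the stretch of chromosome beside S100a4 is a candidate explanation, and it cannot be told apart from a change of the mouse's own gene, because the S100a4 probe stayed near background and 0 of the 12 other S100a probes were higher on every FSP1 ablated array than on every other array. The labels do not describe the transgene, and no biological explanation was tested.

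Single arrays stood far from the rest of their group in 18 of 318 groups tested (5.66%), where chance gives about 1 in 20. Among the healthy arrays, array 1 read 13.01 for Lcn2 (the nearest other array 8.19), 7.45 for Nid1 (the others 7.16 to 7.19), 12.13 for Dcn (11.44 to 11.55), 9.25 for S100a8 (7.69 to 7.84) and 7.57 for Isg15 (8.60 to 8.72). Healthy array 2 read 10.08 for Lgals3 (7.85 to 8.08) and 10.95 for Gpnmb (6.08 to 6.24), and healthy array 4 read 7.96 for S100a11 (8.36 to 8.42) and 7.47 for Dhx58 (7.78 to 7.80). Among the FSP1 ablated arrays, array 1 read 7.39 for Col1a1 (6.53 to 6.63), 8.18 for Col5a1 (7.45 to 7.54) and 10.26 for Sparc (9.20 to 9.29), array 3 read 9.29 for S100a11 (10.65 to 10.80) and 6.82 for Glul (6.21 to 6.27), and array 4 read 9.62 for Elovl6 (11.64 to 11.95). Among the CCl4 arrays, array 3 read 14.18 for Lcn2 (13.06 to 13.34) and 8.35 for Col6a1 (9.01 to 9.35), and array 1 read 6.81 for Fasn (6.19 to 6.36).

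The numbers of calls were set beside other splits of the same arrays into groups of the same sizes. Between CCl4 and healthy liver 1 of 100 splits, the real one, gave as many genes (4387, highest other 2364). The real split also gave the most genes between FSP1 ablated and CCl4 liver (1 of 100, 1673, highest other 722) and between the ablations (1 of 35, 585, highest other 249). The same held between FSP1 ablated and healthy liver (1 of 35, 2285, highest other 851) and between aSMA ablated and healthy liver (1 of 35, 2912, highest other 2635). With 35 splits, 1 of 35 is the smallest share possible, and the shares were not adjusted for the number of comparisons. Between ablated and healthy liver the real split also parts the arrays by sex signal and deposited scale. Between CCl4 and healthy liver it also parts them by deposited scale. Between the ablations, and between aSMA ablated and healthy liver, it also parts them by Alb set. In these comparisons the splits cannot tell the groups from such differences. Chance cannot be excluded for aSMA ablated against CCl4 liver, where 11 of 84 splits gave at least the 1 gene found. The highest other split there called 1698 genes by setting CCl4 arrays 1 to 3 against the rest, which points to a structure of the CCl4 arrays. For the gene lists, the real split gave the most for FSP1 ablated against healthy liver (1 of 35, 25 lists, highest other 22). It also did for aSMA ablated against healthy liver (1 of 35, 18, highest other 17), with the same limits of sex signal, scale and number of splits. Chance cannot be excluded for the number of lists between CCl4 and healthy liver (9 of 100, 20, highest other 23) and FSP1 ablated and CCl4 liver (11 of 100, 17, highest other 18). Nor can it for aSMA ablated and CCl4 liver (5 of 84, 17, highest other 19) and the ablations (11 of 35, 15, highest other 19).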

How the results depend on the processing

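Chosen after the data were seen were same-sex arrays, the parts of the CCl4 arrays, the Alb set block, and the list tests with these, with the sex block, with centring and without single arrays. The other alternatives were planned. Same-sex arrays set both ablations against CCl4 arrays 1 to 3, and CCl4 arrays 5 and 6 against the healthy arrays. Their fold changes are those of arrays 1 to 3 and, against healthy liver, those of the sex block. Offsets 16 and 50 were both in the design, 16 for a table with detection p and 50 as the alternative and the fallback. The fallback was used, and 16 became the alternative. The planned slide block was not run, since no slide is given. Dim genes near background, such as S100a4, carry little information on direction. The cause of the changes below was not tested, except that fewer arrays or groups leave less to estimate the spread from.

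For CCl4 against healthy liver 4387 genes (2165 higher, 2222 lower) became 8583 (8515 higher, 68 lower) on the deposited scale, 7123 (6367 higher, 756 lower) with median centring, 2479 with the sex block and 2861 with same-sex arrays, and leaving out 1 array gave 3415 to 4727. For FSP1 ablated against CCl4 liver 1673 became 2301 with array weights and 2172 against CCl4 arrays 4 to 6, and leaving out 1 array gave 1111, without FSP1 ablated array 2, to 1757. For aSMA ablated against CCl4 liver the 1 gene became 0 with quantile normalization alone, on the deposited scale, with offset 16, with trend and robust variances and with only the groups compared, where limma gave 1323, 1243, 1364, 1314 and 1305 genes at unadjusted p under 0.05. It became 3 with every probe on its own, 10 (9 higher, 1 lower) with centring, 22 with the replicate block, 220 with the sex block, 1688 with array weights, 1405 with same-sex arrays, 1236 against CCl4 arrays 1 to 3, 4 against arrays 4 to 6 and 4 with the Alb set block, and 0 to 189 without 1 array. Same-sex arrays and arrays 1 to 3 hold the same fold changes here, as do arrays 4 to 6 and the Alb set block, so these are not separate checks. For FSP1 against aSMA ablated liver 585 (246 higher, 339 lower) became 333 (104 higher, 229 lower) on the deposited scale, 2563 with array weights, 302 with the Alb set block and 97 to 705 without 1 array, and 836 (197 higher, 639 lower) with centring.

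For FSP1 ablated against healthy liver 2285 (1172 higher, 1113 lower) became 9238 (9178 higher, 60 lower) on the deposited scale, 6460 (6110 higher, 350 lower) with centring, 4028 with array weights, 165 with the sex block and 1359 to 2966 without 1 array. For aSMA ablated against healthy liver 2912 (1461 higher, 1451 lower) became 8367 (8306 higher, 61 lower), 6811 (6333 higher, 478 lower), 4776 and 1358 under these, and 1601 to 3547 without 1 array. The median change of all genes against healthy liver was -0.02, 0.00 and -0.01 with the settings of the report. It stood at 1.03, 1.17 and 1.10 on the deposited scale in the order CCl4, FSP1 and aSMA, and at 0.32, 0.33 and 0.38 with centring.

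With an estimated correlation camera called 0 lists in each comparison, with 8, 7, 7, 3, 9 and 5 at unadjusted p under 0.05 in the order CCl4 against healthy, FSP1 against CCl4, aSMA against CCl4, FSP1 against aSMA, FSP1 against healthy and aSMA against healthy, where the preset gave 20, 17, 17, 15, 25 and 18 and fry 29, 15, 2, 0, 25 and 22. On the deposited scale the lists were 12 for CCl4 against healthy, 13 for FSP1 ablated against healthy and 9 for aSMA ablated against healthy, and with centring 11, 9 and 7. For FSP1 ablated against CCl4 they were 9 with the replicate block, 9 with the sex block, 11 with same-sex arrays and 11 against CCl4 arrays 1 to 3. For aSMA ablated against CCl4 they were 8 with same-sex arrays and 8 against CCl4 arrays 1 to 3, and for aSMA ablated against healthy 11 with the sex block. Without 1 array they ranged over 20 to 23, 12 to 18, 13 to 19, 13 to 16, 18 to 25 and 16 to 21 in the order above. The share of CCl4 genes with the opposite sign was 48.7% under FSP1 ablation and 49.5% under aSMA ablation on the deposited scale, and 59.1% under aSMA ablation with CCl4 arrays split. The correlation of the ablations was 0.336 on the deposited scale and 0.315 with CCl4 arrays split.

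Of the 4387 genes of CCl4 against healthy liver 3181 passed on the deposited scale, 2226 of them with the same sign. The counts were 1652 and 1232 for FSP1 ablated and 2044 and 1513 for aSMA ablated against healthy liver. With centring they were, in the same order, 2775 and 2383, 1443 and 1300, and 1855 and 1624. Of the genes named in the report or the other parts, those that changed sign had not passed with the settings of the report. S100a4 against healthy liver turned to 0.85 for CCl4, 0.92 for FSP1 and 0.44 for aSMA on the deposited scale, with adjusted p = 0.00503 and 0.00553 for the first and second. For CCl4 it was 0.03 with the sex block, 0.02 with centring, 0.03 with same-sex arrays and -0.08 to 0.02 without 1 array, and for FSP1 against healthy 0.03 with the sex block. For FSP1 ablated against CCl4 liver S100a4 was 0.06 on the deposited scale, 0.00 with the replicate block and 0.00 with the sex block, and Alb was 0.03 with same-sex arrays. Those CCl4 arrays are the part with a low Alb signal, so this value is no test of Alb. Col1a1 under aSMA ablation against CCl4 was 0.12 with same-sex arrays, 0.12 against CCl4 arrays 1 to 3 and -0.62 to 0.19 without 1 array. Cyp2e1 between the ablations was 1.41 with the Alb set block and -0.31 to 0.05 without 1 array. For FSP1 ablated against healthy liver Acta2 was 1.07 on the deposited scale, 0.40 with centring and -0.48 to 0.06 without 1 array, Cyp2e1 was 0.06 on the deposited scale and 0.38 with the sex block, Timp1 was -0.13 with the sex block, Col3a1 was -0.09 to 0.20 and Alb -0.04 to 0.11 without 1 array. For aSMA ablated against healthy liver Cyp2e1 was 0.12 on the deposited scale and 0.46 with the sex block, and Acta2 was -0.04 with the sex block and -0.15 to 0.77 without 1 array. Of the values of named genes under the alternatives, 4038 kept their direction and side of the threshold, 139 lost the threshold, 106 gained it and 32 reversed.

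Deviations of arrays of the same replicate number in different groups correlated at -0.303 to 0.38 over 21 pairs, 6 of them above 0.1. Among the arrays numbered 2 of the CCl4-treated groups they were 0.38 (CCl4 and aSMA ablated), 0.244 (FSP1 ablated and CCl4) and 0.173 (both ablations). Arrays of unlike number were not compared, so whether arrays of 1 number share a deviation cannot be told. The numbers were not read as pairs. The replicate block moved the number of genes by over 1.5 times only for aSMA ablated against CCl4 liver.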

Other observations

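The list results here follow the planned test, and the checks against parts of the CCl4 arrays, with the sex block, with centring and without single arrays were chosen after the data were seen. Lists called in several comparisons are not described in every one. All 6 erythroid genes were lower after FSP1 ablation than in healthy liver at a median of -1.39, 6 also when adjusted over the list alone (adjusted p = 2.92e-05, and adjusted p = 0.162 with an estimated correlation). In CCl4 liver 4 of the 6 were lower than in healthy liver at a median of -0.70, 4 also when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.343 with an estimated correlation), a list that had adjusted p = 0.111 with the sex block. Between FSP1 ablated and CCl4 liver the list did not pass (adjusted p = 0.0532). Neutrophil markers were higher than in healthy liver in 8 of 14 cases after FSP1 ablation, 9 when adjusted over the list alone (adjusted p = 1.18e-05, and adjusted p = 0.243 with an estimated correlation), in 7 after aSMA ablation, 8 when adjusted over the list alone (adjusted p = 0.00161, and adjusted p = 0.431 with an estimated correlation), and in 2 in CCl4 liver, 2 also when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.493 with an estimated correlation). On the deposited scale none of these 3 neutrophil results passed (adjusted p = 0.253, 0.38 and 0.555 in the order given), nor with centring (adjusted p = 0.316, 0.668 and 0.955). Under FSP1 ablation against CCl4 liver the neutrophil list had a median of 0.30, with 0 passing over all genes or when adjusted over the list alone (adjusted p = 0.0269, adjusted p = 0.571 with an estimated correlation, 0.13 on the deposited scale and 0.0563 with centring). Under aSMA ablation it had a median of 0.14, again with 0 (adjusted p = 0.0383, adjusted p = 0.7 with an estimated correlation, 0.112 on the deposited scale and 0.106 with centring). Against CCl4 arrays 1 to 3 these had adjusted p = 0.421 and 0.952, and against arrays 4 to 6 adjusted p = 0.00283 and 2.95e-05. Calls remained in 6 of 10 and 5 of 9 fits without 1 array, with adjusted p = 0.211 without FSP1 ablated array 3 and 0.52 without aSMA ablated array 1. Of 12 Kupffer cell markers, those of the resident macrophages of liver, 4 rose and 1 fell under FSP1 ablation against CCl4 liver, 5 and 1 when adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.48 with an estimated correlation). They include Slc40a1, the iron exporter (0.77, SE 0.14; adjusted p = 0.00198), Fcna, a ficolin (0.66, SE 0.13; adjusted p = 0.00345) and Cd163, the scavenger receptor for haemoglobin (0.95, SE 0.20; adjusted p = 0.00475), and the list had adjusted p = 0.0645 against CCl4 arrays 1 to 3 and 0.0553 with the replicate block.

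Matrix proteases rose in CCl4 liver in 13 of 19 cases, 13 also when adjusted over the list alone (adjusted p = 7.44e-05, and adjusted p = 0.0501 with an estimated correlation), with Mmp2 at 1.83 (SE 0.29; adjusted p = 0.000238). Contractile genes rose in 9 of 13 cases, 10 when adjusted over the list alone (adjusted p = 0.00028, and adjusted p = 0.284 with an estimated correlation), with Tpm1 at 1.94, and cytokine, chemokine and NF-kB genes in 12 of 25, 12 also when adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.284 with an estimated correlation). Portal fibroblast markers rose in 7 of 14 cases, 8 when adjusted over the list alone (adjusted p = 0.00103, and adjusted p = 0.284 with an estimated correlation), stellate cell markers in 6 of 15, with 1 that fell, 7 and 1 when adjusted over the list alone (adjusted p = 0.0119, and adjusted p = 0.323 with an estimated correlation), TGF-beta genes in 7 of 15, with 1 that fell, 7 and 2 when adjusted over the list alone (adjusted p = 0.00908, and adjusted p = 0.251 with an estimated correlation), and p53 targets in 7 of 18, with 2 that fell, 9 and 2 when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.194 with an estimated correlation). Tgfbr2, a TGF-beta receptor, rose by 1.90 (SE 0.20; adjusted p = 5.04e-06). With each array centred on its median the 7 lists of this paragraph so far no longer passed, with adjusted p from 0.0908 to 0.691. Interferon genes rose in 8 of 26 cases and fell in 1, 8 and 1 also when adjusted over the list alone (adjusted p = 0.0119, and adjusted p = 0.493 with an estimated correlation), with adjusted p = 0.0861 without healthy array 1. Immediate early genes rose in 5 of 13 cases, 6 when adjusted over the list alone (adjusted p = 0.0251, and adjusted p = 0.493 with an estimated correlation), and had adjusted p = 0.4 with the sex block and 0.0522 without CCl4 array 4.

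Bile acid genes fell in CCl4 liver in 10 of 19 cases, with 1 that rose, 11 and 1 when adjusted over the list alone, at a median of -0.40 that was 0.32 on the deposited scale and 0.04 with centring (adjusted p = 0.00181, and adjusted p = 0.284 with an estimated correlation). Cyp27a1, an enzyme of bile acid synthesis, changed by -1.46 (SE 0.24; adjusted p = 0.000331), and by -0.60 (adjusted p = 0.077) on the deposited scale. Cholesterol synthesis genes fell in 8 of 18 cases, 8 also when adjusted over the list alone, at a median of -0.48 that was 0.51 on the deposited scale and 0.16 with centring (adjusted p = 0.0251, and adjusted p = 0.493 with an estimated correlation). That list had adjusted p = 0.0663 without CCl4 array 4. Under FSP1 ablation against CCl4 liver 4 cholesterol genes fell and 1 rose, 7 and 1 when adjusted over the list alone (adjusted p = 0.00433, and adjusted p = 0.49 with an estimated correlation), with Dhcr7, the last enzyme of the pathway, at -1.34 (SE 0.26; adjusted p = 0.00258). Without FSP1 ablated array 4 the list had adjusted p = 0.0615 in this comparison.

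Under FSP1 ablation against CCl4 liver, lipogenesis genes rose in 5 of 22 cases and fell in 2, 9 and 2 when adjusted over the list alone (adjusted p = 0.0399, and adjusted p = 0.571 with an estimated correlation), with Elovl6, which lengthens fatty acids, at 2.31 (SE 0.46; adjusted p = 0.00347), and the list had adjusted p = 0.249 without FSP1 ablated array 2. Acute phase genes rose in 5 of 20 cases and fell in 1, 5 and 1 also when adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.602 with an estimated correlation), with adjusted p = 0.0791 without FSP1 ablated array 4. Complement and coagulation genes rose in 6 of 24 cases, with 9 that rose and 3 that fell when adjusted over the list alone (adjusted p = 0.0266, and adjusted p = 0.571 with an estimated correlation), among them the clotting factor genes F7 (0.83, SE 0.12; adjusted p = 0.000201) and F12 (0.84, SE 0.12; adjusted p = 0.000288), and that list had adjusted p = 0.823 against CCl4 arrays 4 to 6 and 0.096 without FSP1 ablated array 3. Female-biased liver genes rose in 4 of 10 cases, 4 also when adjusted over the list alone (adjusted p = 0.00433, and adjusted p = 0.317 with an estimated correlation), with adjusted p = 0.11 against CCl4 arrays 1 to 3. Oxidative phosphorylation genes had a median of -0.21 with 1 of 21 lower, 5 when adjusted over the list alone (adjusted p = 0.00369, and adjusted p = 0.49 with an estimated correlation), and adjusted p = 0.267 with centring.

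Under aSMA ablation against CCl4 liver complement and coagulation genes had a median of 0.25, with 2 higher when adjusted over the list alone (adjusted p = 8.64e-06, and adjusted p = 0.296 with an estimated correlation), and adjusted p = 0.327 against CCl4 arrays 4 to 6. Hepatocyte secreted proteins had a median of 0.07, with 0 when adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.204 with an estimated correlation). This list holds Alb, whose probe parts the arrays and which differed by 1.27 (adjusted p = 0.384 by limma). MHC class II genes had a median of 0.09, with 1 higher when adjusted over the list alone (adjusted p = 0.0161, adjusted p = 0.564 with an estimated correlation, 0.15 on the deposited scale and 0.08 with centring). That list had adjusted p = 0.0833 against CCl4 arrays 1 to 3, 0.0741 against arrays 4 to 6 and 0.326 without aSMA ablated array 1. No single gene of these lists passed in this comparison over all genes. Against healthy liver 7 of 14 MHC class II genes were higher after aSMA ablation, 8 when adjusted over the list alone (adjusted p = 0.00387, adjusted p = 0.431 with an estimated correlation, 0.746 on the deposited scale and 0.842 with centring), and the list had adjusted p = 0.0525 with the sex block.

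Between the ablations, MHC class II genes (adjusted p = 0.0132, and 0.143 on the deposited scale; 4 lower when adjusted over the list alone), glutathione transferase genes (adjusted p = 0.0411, and 0.0924 with centring; 3 lower) and fatty acid oxidation genes (adjusted p = 0.00768; 2 lower) were lower as lists after FSP1 ablation, with adjusted p = 0.589, 0.589 and 0.497 with an estimated correlation, and each lost its call without at least 1 array, at adjusted p up to 0.149, 0.41 and 0.105. Endoplasmic reticulum stress genes (adjusted p = 0.0097; 1 higher when adjusted over the list alone) and inhibitors of matrix proteases (adjusted p = 0.0384; 2 higher) were higher after FSP1 ablation than in healthy liver, with adjusted p = 0.295 and 0.241 with an estimated correlation, and 0.0584 and 0.0612 without healthy arrays 1 and 4 respectively. Lists called in no comparison were T and NK cell, B and plasma cell, endothelial, cholangiocyte, pancreatic acinar and adipocyte markers, the S100 family, sex-linked genes, heat shock and hypoxia genes, 10 lists whose smallest adjusted p was 0.0549, for B and plasma cell markers.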
